A study of Rattus norvegicus with 10 samples.

How the data were processed

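Retinal RNA of 3-day-old rats of the strains F344 and SD was hybridised to Affymetrix whole-transcript rat gene arrays, 10 arrays in all. Each array held 1 pool of RNA from 3 rats of 2 litters. The groups were F344 in cyclic hyperoxia (3 pools), F344 in room air (2 pools), SD in cyclic hyperoxia (2 pools) and SD in room air (3 pools), taken from the sample titles and the strain labels. The study's design text says that 1 array of F344 hyperoxia and 1 of SD room air were added after a principal component analysis of the first 8. The arrays numbered 3 of those groups were taken to be the added ones. That is an inference from the numbering.

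The deposited values are log2 expression values per probe set, given to 1 decimal, between 3.1 and 14 in every array. RMA, which models the probes of a probe set together and returns log2 values, and Partek 6.4 are named per the submitters' processing notes, with no role or order. The background correction, the scaling step and the annotation used by the authors are not given in the sources used here. Rounding to 1 decimal puts a floor under small differences, and array medians lay between 5.9 and 6. The number of arrays limits the precision, and probe-level signal over background was not analysed here.

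The table held 27342 probe sets. Of these, 15097 had 1 gene symbol in the platform annotation, 323 had several and 11922 had none there. All probe sets entered the fit, and only those with 1 symbol were named. Each of the 14324 genes was counted by its probe set with the highest mean over all arrays, and 499 genes had several probe sets. The entrez identifiers of 15067 of the singly named probe sets were in a current gene table of the assembly GRCr8, which served for current symbols and for the order of genes only. A rule that a listed symbol is followed to a newer name only where it is not itself the current symbol of another gene was set after the data were seen, because 5 listed symbols had been matched to other genes.

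Tests were run in R 4.3.3 with limma 3.58.1. One model with a mean per group was fitted to all 10 arrays (6 residual degrees of freedom), followed by eBayes with default settings, two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The contrasts were hyperoxia minus room air in SD and in F344, the difference of these effects (SD minus F344), their average, and SD minus F344 in room air and in hyperoxia. Gene lists were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01, adjusted over the lists within a contrast. In the alternative, camera estimated that correlation from the data. The function fry was run too. Its directional p tests whether a list's genes move, on balance, one way, and its mixed p whether they change in either direction; neither compares a list with other genes.

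The groups, contrasts, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Of the 32 lists fixed, 31 had at least 5 measured members and were tested. The list of Y-linked genes and Xist had none measured. Some lists share members, so their results are not independent. The hypoxia-inducible factor list shares genes with the glycolysis and angiogenic lists, and the angiogenic list with the endothelial, tip cell and pericyte lists. The lists covered hypoxia-inducible factor targets, glycolysis, angiogenic factors, endothelial cells, tip cells, pericytes, astrocytes, progenitors and Mueller glia, cell cycle, ganglion, amacrine and horizontal, photoreceptor and bipolar cells, lens, pigment epithelium, erythroid cells, skeletal muscle, surface epithelium, fibroblasts, microglia, antioxidant defence, p53 targets, the unfolded protein response, cholesterol synthesis, immediate early genes, the circadian clock, interferon response, inflammatory cytokines, respiratory chain, ribosomal proteins and RT1 genes. A published account of this study is known to name Egln3, Bnip3, Slc16a3 and Hk2, so the direction of these 4 hypoxia-list members is not independent evidence, and the list was also tested without them.

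The rule for named genes took, per contrast, the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap. Where fewer than 10 genes passed, it took all of them and the 10 with the smallest p after them. It also took up to 4 passing members of each list, or up to 2 with the largest change where none passed, and Vegfa, Egln3, Bnip3, Slc16a3, Hk2, Epo, Hmox1, Kdr, Pecam1 and Gfap. Kdr and Pecam1 had no singly named probe set in the annotation used. Other members are named where they illustrate a group and were chosen after their values were seen.

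The alternatives were the brighter part of the probe sets, trend and robust eBayes, repeated quantile normalization, median centring, array weights, 1 probe set per gene, the mean of a gene's probe sets, only the groups compared, the replicate number as a block, the 8 arrays without those numbered 3, a term in the model for these 2 arrays (called the added-array term), a threshold of 0.1, and each array left out in turn. The added-array term in list tests, correlations and single genes, and a fit with that term and without F344 hyperoxia pool 2, were chosen after seeing the data.

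The fit was tested on simulated data with 200 genes changed by exposure in SD, over 14324 genes and 5 simulated sets. With a shift added to the arrays numbered 3, it recovered 12% of genes changed by 0.5 on the log2 scale, 72% at 1, 93.6% at 1.5 and 98.4% at 2, with a mean of 1.2 false calls. Without the shift the mean was 3.2 false calls, and with the added-array term it was 3.4 with or without the shift. The simulated noise was independent between probe sets, and its spread came from a fit without the term, so it already held that shift. In 600 simulated unchanged lists of 43 genes, for the difference of exposure effects, camera with the preset correlation called 51% at an unadjusted p of 0.05 where members were correlated at 0.281, and 4.33% with an estimated correlation. With uncorrelated members the shares were 1.83% and 1.17%. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.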

Results

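Gene expression was measured in whole retinas of rats at postnatal day 3 after cyclic hyperoxia, the exposure that precedes oxygen-induced retinopathy, a rodent model of retinopathy of prematurity. Litters were placed in the chamber within 12 hours of birth and passed through 24-hour periods of 80% and 21% oxygen in turn. The design describes F344 rats as resistant and SD rats as susceptible. There were 3 pools of F344 and 2 of SD in hyperoxia, and 2 pools of F344 and 3 of SD in room air, each pool holding RNA of 3 rats. Fold changes below are on the log2 scale with their standard error (SE), and adjusted p-values are from limma unless camera is named.

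The first principal component held 34.1% of the variance and set F344 hyperoxia pool 3 (30.08) and SD room-air pool 3 (36.41) apart from the other 8 arrays, which lay at or below -1.765. In these arrays 25 of 39 cell cycle genes were lower and 8 of 31 photoreceptor genes higher than the other arrays of their groups, by the added-array term. Of all 14324 genes, 1058 were higher and 1251 lower. Of hypoxia-inducible factor targets 10 were lower and 1 higher (median -0.15), and of glycolysis genes 5 were lower and 0 higher (median -0.20). Camera called both lists down (adjusted p = 0.0113 each, and 0.579 and 0.55 with an estimated correlation). One of these arrays is a hyperoxia pool and the other a room-air pool, of opposite strains. Their shift thus enters the exposure effects of SD and F344 with opposite signs. Only a shift of equal size in both arrays would cancel in the average of both effects.

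In SD, cyclic hyperoxia lowered genes of the response to low oxygen. Igfbp2, which encodes a binding protein of insulin-like growth factors, fell by 1.85 on the log2 scale (SE 0.127, 3.61-fold lower, adjusted p = 1.23e-04), and Slc16a3, the lactate exporter of glycolytic cells, fell by 1.98 (SE 0.243, 3.95-fold, adjusted p = 0.0149), with 2 hyperoxia and 3 room-air pools. Bnip3, a receptor for the removal of mitochondria, fell by 1.60 (SE 0.214) and Cox4i2, the hypoxia-inducible isoform of a cytochrome oxidase subunit, fell by 1.43 (SE 0.153). Pdk1, a kinase that keeps pyruvate out of mitochondria, fell by 1.25 (SE 0.137), Fam162a fell by 1.02 (SE 0.122) and the cytokine gene Mif fell by 0.95 (SE 0.141). These 7 genes made up the count, and 0 rose by limma, although 1 probe set not counted as a gene did. In all, 1628 of 27342 probe sets had an unadjusted p under 0.05 in either direction, a share slightly above the 0.05 expected without any effect.

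Next in order of p, and not passing, were Vegfa, the main angiogenic growth factor of the retina, at -1.18 (SE 0.18, adjusted p = 0.0526), Etv5 at -0.83, Egln3, an oxygen-sensing prolyl hydroxylase, at -1.53 (SE 0.259, adjusted p = 0.114), Ak4 at -1.03, the glycolytic regulator Pfkfb3 at -1.40, Selenom at -0.87, Pfkl at -0.83, Loxl2 at -0.85, Spr at -0.68 and P4ha1 at -1.05. Hk2, a hexokinase, stood at -1.28 (SE 0.349, adjusted p = 0.746, and 0.0204 with the added-array term). Hmox1 stood at -0.45, Epo at -0.03 and Gfap, the astrocyte filament gene, at -0.05. With SD hyperoxia pool 1, SD hyperoxia pool 2 or SD room-air pool 2 left out, 1 gene passed, with SD room-air pool 1 left out 2, and with either F344 room-air pool left out 4. Igfbp2 passed without each of the 10 arrays in turn, Cox4i2 in 7 of these fits, Pdk1 and Fam162a in 6, Slc16a3 in 4, Bnip3 in 2 and Mif in 1. With the added-array term 17 genes passed, among them these 7 and Vegfa (adjusted p = 0.0204). Without both arrays numbered 3, 1 passed.

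Of 43 measured targets of hypoxia-inducible factor, 38 lay below 0 in SD, with a median of -0.45. Of these, 5 fell (Slc16a3, Bnip3, Pdk1, Fam162a and Mif), 0 rose and 38 did not pass; adjusted over the list alone, 25 fell. The list shifted down by camera (adjusted p = 1.79e-32, adjusted p = 0.182 with an estimated correlation). Without the 4 members the study is known to name, the median of the other 39 was -0.42 (adjusted p = 1.62e-25, adjusted p = 0.182 with an estimated correlation). In no comparison did a list call of the fit without the added-array term hold with an estimated correlation. List calls of the comparisons with that term were not tested with it.

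Of 19 glycolysis enzymes and transporters, 17 lay below 0 in SD (median -0.43), Slc16a3 fell, and 10 fell adjusted over the list alone, among them Tpi1 at -0.75 (SE 0.148), Aldoa at -0.62 (SE 0.122) and Gpi at -0.62 (SE 0.127). Camera placed the list down (adjusted p = 6.57e-16, adjusted p = 0.201 with an estimated correlation). It shares members with the hypoxia-inducible factor targets, among them Slc16a3, Hk2 and Pgk1, so the falls of these lists are not separate evidence. Markers of vessels also lay low. Of 24 endothelial genes 22 were below 0 (median -0.27, adjusted p = 5.85e-10, adjusted p = 0.201 with an estimated correlation), with 0 passing and 2 falling adjusted over the list alone. The lowest were Cd34 at -0.82 (SE 0.171) and the tight-junction gene Cldn5 at -0.58 (SE 0.134). Of 13 pericyte and smooth muscle genes 11 were below 0 (median -0.25, with Rgs5 at -0.72, adjusted p = 1.15e-04, adjusted p = 0.2 with an estimated correlation), and all 12 tip cell genes were below 0 (median -0.13, adjusted p = 2.30e-04, adjusted p = 0.182 with an estimated correlation). In the arrays numbered 3, endothelial genes were higher by a median of 0.18 by the added-array term, and with that term the endothelial median in SD was -0.24. The pericyte mean in SD was -0.222, and -0.142 without SD room-air pool 3. In every pool of both strains the endothelial (5.088 to 5.567) and pericyte (5.208 to 5.623) list means lay below the array medians (5.9 to 6). Both lists thus lay on average among the dimmer probe sets, for which signal over background was not analysed.

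Other lists were called in SD as well. Of 34 ribosomal protein genes 28 lay below 0 (median -0.17, adjusted p = 3.79e-06, adjusted p = 0.381 with an estimated correlation), 5 of them falling adjusted over the list alone, among them Rpl24 at -0.53 (SE 0.166). Of 34 respiratory chain genes 27 lay below 0 (median -0.14, adjusted p = 0.0032, adjusted p = 0.472 with an estimated correlation), a call that ended without SD hyperoxia pool 2 (adjusted p = 0.156), without SD room-air pool 3 (adjusted p = 0.112) and with the added-array term (adjusted p = 0.178). Angiogenic factors and receptors had a median of -0.10 (adjusted p = 0.00391, adjusted p = 0.271 with an estimated correlation, adjusted p = 0.0708 without SD hyperoxia pool 2, adjusted p = 0.083 without both arrays numbered 3), with Vegfa and Adm falling adjusted over the list alone. Of 39 cell cycle genes 35 lay above 0 (median 0.13, adjusted p = 0.00194, adjusted p = 0.577 with an estimated correlation), led by Mcm5 at 0.40 (SE 0.269). By the added-array term cell cycle genes had a median of -0.375 in the arrays numbered 3, and without SD room-air pool 3 the mean change in SD turned from 0.129 to -0.018 (adjusted p = 0.558), while it was 0.194 without SD room-air pool 1 and 0.21 without SD room-air pool 2.

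**Figure D1:**
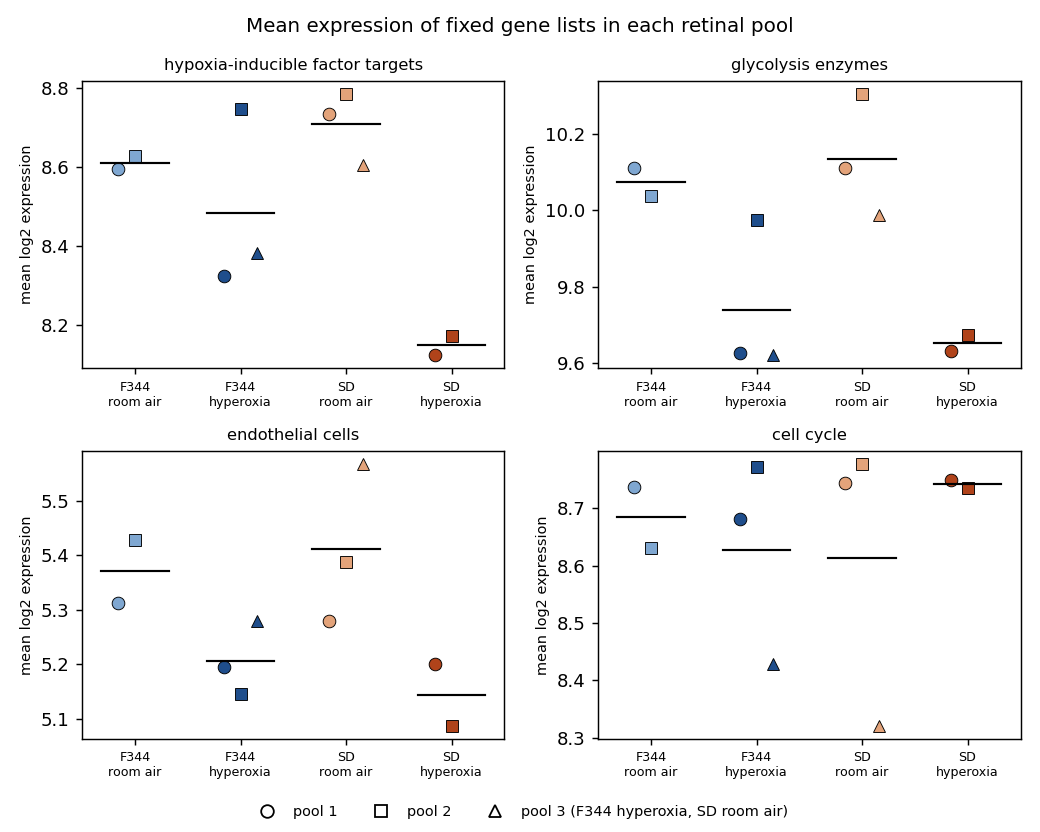
Mean log2 expression of the members of 4 fixed lists in each retinal pool, by strain and exposure; each point is a pool and each bar a group mean. For hypoxia-inducible factor targets both SD hyperoxia pools (8.123 and 8.172) lay below the 3 SD room-air pools (8.605 to 8.784), while F344 hyperoxia pool 2 (8.747) lay above both F344 room-air pools.

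In F344, 1 gene passed. Adra1b, an alpha-adrenergic receptor, fell by 1.03 (SE 0.11, 2.05-fold, adjusted p = 0.0173, 3 hyperoxia and 2 room-air pools); in SD it stood at -0.13. Igfbp2 stood at -0.87 (SE 0.127, adjusted p = 0.233, and 0.0145 with the added-array term), followed by the matrix genes Fn1 at -0.65 and Fbln2 at -0.60, Loxl2, a collagen cross-linking enzyme, at -0.83, Pdlim1 at 0.53, Surf2 at 0.50, Cacna1h at -0.52, the glial potassium channel gene Kcnj10 at -0.53, Pdgfra, a marker of astrocyte precursors, at -0.53 and Cbln4 at -0.55, with adjusted p between 0.715 and 0.921. Slc16a3 stood at -0.95 (SE 0.243), Hk2 at -0.37 (SE 0.349), Vegfa at -0.20, Egln3 at -0.18, Bnip3 at -0.15, Hmox1 at -0.20, Epo at -0.05 and Gfap at -0.02. The count of rising genes was 0 by limma. At an unadjusted p under 0.05 in either direction were 1320 of 27342 probe sets, a share below the 0.05 expected without any effect. Leaving out any 1 array other than those numbered 3 left 0 genes, as did the fit without both of those.

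Of the 43 hypoxia-inducible factor targets, 30 lay below 0 in F344 (median -0.15); 0 passed, and 3 fell adjusted over the list alone. Camera placed the list down (adjusted p = 0.00224, adjusted p = 0.786 with an estimated correlation). The list mean was -0.126 (SE 0.131 over pools). It was -0.045 without F344 hyperoxia pool 1 (adjusted p = 0.4), -0.257 (SE 0.064) without pool 2, -0.074 without pool 3 and -0.074 (SE 0.13) with the added-array term. The pools of F344 hyperoxia differed here: relative to the F344 room-air mean, 34 members lay lower in pool 1, 31 in pool 3 and 13 in pool 2. The 19 glycolysis genes lay lower (median -0.37, 9 falling adjusted over the list alone, among them Aldoa at -0.50 and Pgk1 at -0.63, adjusted p = 1.06e-10, adjusted p = 0.34 with an estimated correlation). So did endothelial genes (median -0.15, adjusted p = 3.98e-05, adjusted p = 0.425 with an estimated correlation) and pericyte genes (median -0.13, with Notch3 at -0.57, adjusted p = 0.0027, adjusted p = 0.34 with an estimated correlation). The endothelial mean was -0.164, and -0.106 without F344 room-air pool 2. Angiogenic factors and receptors had a median of -0.08 (adjusted p = 0.00484, adjusted p = 0.34 with an estimated correlation), and that call ended without F344 hyperoxia pool 1 (adjusted p = 0.0976) or F344 room-air pool 2 (adjusted p = 0.0627).

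Photoreceptor, respiratory chain, ribosomal protein and unfolded protein genes lay higher in exposed F344, while ganglion, amacrine and bipolar cell genes were not called (adjusted p = 0.709, 0.766 and 0.597). Of 31 photoreceptor genes 28 were above 0 (median 0.22, adjusted p = 3.84e-09, adjusted p = 0.311 with an estimated correlation), led by Gngt1 at 1.03 (SE 0.43) and Sag, rod arrestin, at 0.85 (SE 0.23), with 0 passing and 2 rising adjusted over the list alone. Of 34 respiratory chain genes 33 were above 0 (median 0.19, adjusted p = 8.28e-10, adjusted p = 0.425 with an estimated correlation), and of 34 ribosomal protein genes 29 (median 0.13, adjusted p = 1.43e-05, adjusted p = 0.506 with an estimated correlation, and 0.0951 without F344 room-air pool 2). The unfolded protein list had a median of 0.13 (adjusted p = 0.00269, adjusted p = 0.311 with an estimated correlation), led by the cystine transporter gene Slc7a11 at 0.67 and Ddit4 at 0.57. In the arrays numbered 3, one of which is F344 hyperoxia pool 3, respiratory chain genes were higher by a median of 0.20, and photoreceptor and ribosomal protein genes by 0.15 each. Without F344 hyperoxia pool 3 or F344 room-air pool 2 the mean of respiratory chain genes in F344 went from 0.238 to 0.138 and 0.144, and that of ribosomal protein genes from 0.158 to 0.084 and 0.08. With the added-array term the F344 medians were 0.14 for photoreceptor, 0.13 for respiratory chain and 0.11 for ribosomal protein genes.

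**Figure D2:**
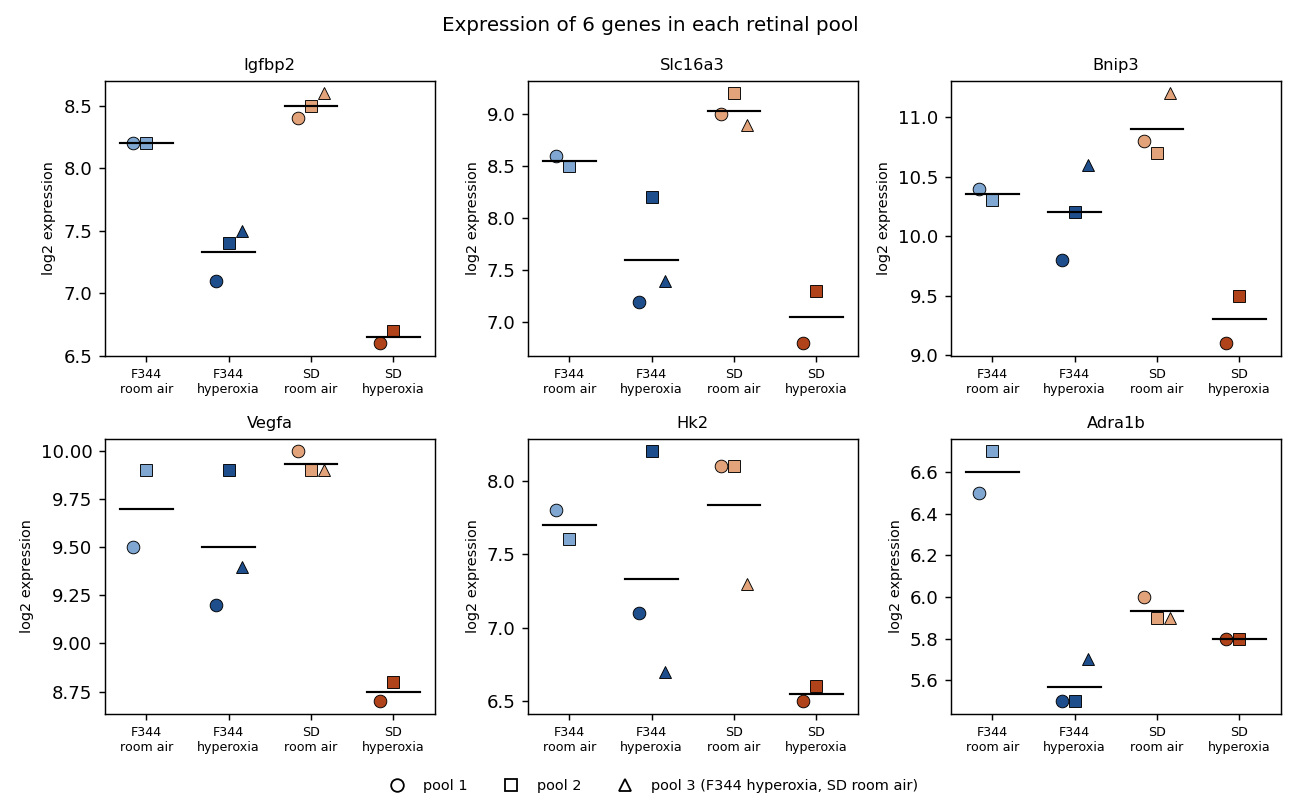
Log2 expression of 6 genes in each retinal pool, by strain and exposure; each point is a pool and each bar a group mean. Igfbp2 lay at 7.1 to 7.5 in the F344 hyperoxia pools against 8.2 in both room-air pools, while Hk2 in F344 hyperoxia pool 2 (8.2) lay above room air (7.8 and 7.6).

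Whether exposure acted differently in the strains was tested as the difference of the effects, SD minus F344. No single gene passed by limma, and 0 passed with the added-array term, the replicate number as a block or without the arrays numbered 3. At an unadjusted p under 0.05 were 2054 of 27342 probe sets, a share above 0.05. The shift of the arrays numbered 3 enters this comparison. The count was 1807 with the added-array term and 1657 without those arrays. The genes with the smallest p (adjusted p = 0.651 each) were Adra1b at 0.90 (SE 0.156), Igfbp2 at -0.98 (SE 0.18), Surf2 at -0.75, Bnip3 at -1.45 (SE 0.303), Spr at -0.88, Pfkfb3 at -1.57 (SE 0.341), Hmg20b at -0.70, Ak4 at -1.12, the vasodilator gene Adm at -0.78 and Bhlhe40, a hypoxia-responsive clock repressor, at -0.98. Vegfa stood at -0.98 (SE 0.255), Egln3 at -1.35, Slc16a3 at -1.03 and Hk2 at -0.92 (SE 0.494).

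As a group, hypoxia-inducible factor targets lay lower in SD than in F344 after subtraction of room air, with 34 of 43 members below 0 (median -0.30), 0 passing and 13 falling adjusted over the list alone. Camera called the list (adjusted p = 1.91e-10, adjusted p = 0.476 with an estimated correlation). The mean over members differed by -0.434 (SE 0.186 over pools), and by -0.302 (SE 0.087) without F344 hyperoxia pool 2. Glycolysis genes (median -0.12, adjusted p = 0.207), endothelial genes (median -0.11, adjusted p = 0.207) and pericyte genes (median -0.05, adjusted p = 0.733) were not called by camera, which does not show that the strains responded alike, and with the added-array term the glycolysis adjusted p was 5.67e-04. Medians were also below 0 for ribosomal protein (-0.36, adjusted p = 5.20e-09, adjusted p = 0.476 with an estimated correlation), respiratory chain (-0.35, adjusted p = 5.20e-09, adjusted p = 0.485 with an estimated correlation) and photoreceptor genes (-0.28, adjusted p = 4.69e-05, adjusted p = 0.476 with an estimated correlation). With the added-array term these were -0.20, -0.15 and -0.10. The unfolded protein list (median -0.22, adjusted p = 0.00542, adjusted p = 0.476 with an estimated correlation) and the antioxidant list (median -0.11, adjusted p = 0.038, adjusted p = 0.476 with an estimated correlation) also lay lower. The antioxidant call ended with the added-array term (adjusted p = 0.101) and without F344 hyperoxia pool 1 (0.0639), F344 room-air pool 2 (0.176), SD hyperoxia pool 2 (0.0636) or SD room-air pool 3 (0.108). Cell cycle genes lay higher (median 0.18, adjusted p = 0.00542, adjusted p = 0.982 with an estimated correlation), a call that ended without F344 hyperoxia pool 3 (adjusted p = 0.154), F344 room-air pool 1 (0.145) or SD room-air pool 3 (0.727), and the mean turned to -0.06 with the added-array term.

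**Figure D3:**
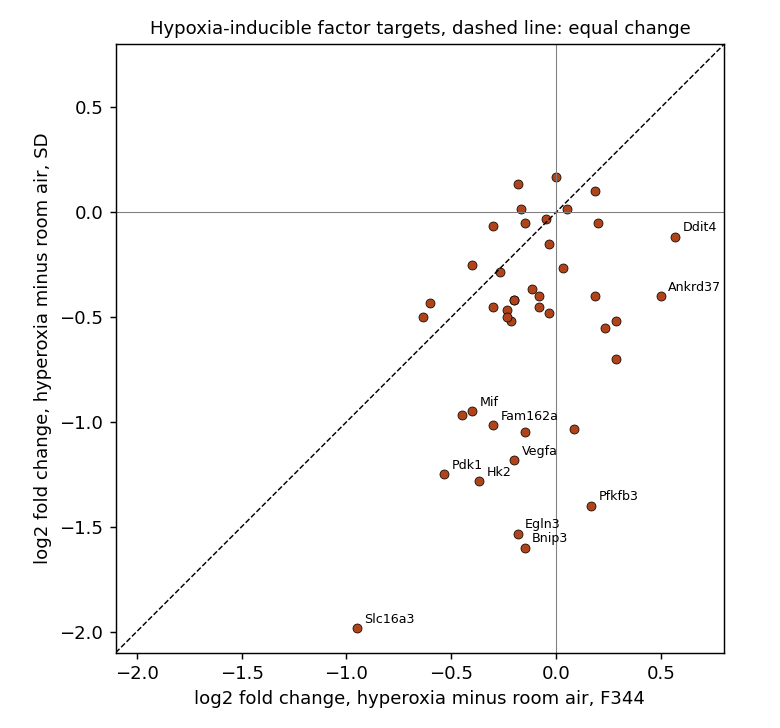
Log2 fold change (hyperoxia minus room air) of the 43 hypoxia-inducible factor targets in SD on the vertical axis against F344 on the horizontal axis; each point is a gene and the dashed line marks equal change. Of the 43, 34 lie below the line, with Slc16a3 the lowest in both strains.

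Across the 14324 genes the effects of both strains had a Pearson correlation of -0.234 and a Spearman correlation of -0.253; genes are not independent replicates, and the contrasts share no arrays. With the added-array term the Pearson value was -0.00951, and it was 0.0435 without F344 hyperoxia pool 3 and -0.0554 without SD room-air pool 3. Over the 43 hypoxia-inducible factor targets it was 0.38. The 7 falls in SD and the 1 in F344 had 0 genes in common, with 0.000489 by the product of sizes. The added-array term gave 17 and 2 falls with 1 gene in common, against 0.00237 by the product of sizes.

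Averaged over both strains, 9 genes fell with hyperoxia and 0 rose by limma. At an unadjusted p under 0.05 were 1115 of 27342 probe sets, a share below the 0.05 expected without any effect. Igfbp2 fell by 1.36 (SE 0.09, adjusted p = 7.96e-05), Slc16a3 fell by 1.47 (SE 0.172), and Cox4i2, Pdk1, Mif, Fam162a and Adra1b fell by 0.58 to 0.98. Loxl2 fell by 0.84 (SE 0.116) and Etv5, a transcription factor downstream of fibroblast growth factor signalling, fell by 0.68 (SE 0.094). Among genes that did not pass, those with the smallest p included the glycolytic enzymes Aldoa at -0.56 (adjusted p = 0.0624), Gpi at -0.56, Pfkl at -0.68 and Tpi1 at -0.62. The rest were glycogen phosphorylase Pygl at -0.68, Smoc1 at -0.43, Bnip3 at -0.88, Fbln2 at -0.48, Gipr at -0.53 and Vegfa at -0.69 (adjusted p = 0.154). Without F344 hyperoxia pool 2, 20 genes fell, and with the added-array term 30. Without either F344 room-air pool, either SD hyperoxia pool or SD room-air pool 2, Igfbp2 alone did, and 2 fell without SD room-air pool 1 and 4 fell without F344 hyperoxia pool 1.

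Of the hypoxia-inducible factor targets 4 fell on average (median -0.28) and 21 fell adjusted over the list alone (adjusted p = 4.48e-32, adjusted p = 0.0617 with an estimated correlation), and of the glycolysis genes 1 and 12 (median -0.37, adjusted p = 6.71e-27, adjusted p = 0.0617 with an estimated correlation). Endothelial genes had a median of -0.21, with 22 of 24 below 0 and 9 falling adjusted over the list alone (adjusted p = 1.56e-15, adjusted p = 0.0669 with an estimated correlation). Pericyte genes had a median of -0.18, with 6 falling adjusted over the list alone (adjusted p = 1.24e-07, adjusted p = 0.0617 with an estimated correlation). Angiogenic factors and receptors had a median of -0.07, with 1 falling adjusted over the list alone (adjusted p = 4.34e-06, adjusted p = 0.0617 with an estimated correlation), and the receptor gene Flt1 stood at -0.39 (SE 0.113). Of 31 photoreceptor genes 25 lay above 0 (median 0.10, adjusted p = 5.75e-05, adjusted p = 0.309 with an estimated correlation), with a mean of 0.106, and 0.069 without F344 hyperoxia pool 3. Of 16 cholesterol synthesis genes 14 lay above 0 (median 0.10, adjusted p = 8.73e-04, adjusted p = 0.31 with an estimated correlation). Respiratory chain genes had a median of 0.05 (adjusted p = 0.0288, adjusted p = 0.603 with an estimated correlation), a call that ended without F344 hyperoxia pool 3 (adjusted p = 0.762), F344 room-air pool 2 (0.739), SD hyperoxia pool 1 (0.213), SD room-air pool 1 (0.292) or both arrays numbered 3 (0.15).

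Between the strains in room air, 79 genes differed, 54 higher and 25 lower in SD (3 SD and 2 F344 pools). Mospd1 was 22.1-fold lower in SD (log2 -4.47, SE 0.144, adjusted p = 1.55e-08), and its other probe set stood at -4.07. Tap2, a peptide transporter subunit, was lower at -2.47 (SE 0.116), its partner Tap1 at -1.12 (SE 0.139) and the immunoproteasome gene Psmb9 at -0.63 (SE 0.11). These 3 lie together in the genome and were the 3 falls among 27 interferon and antigen presentation genes, a list that camera did not call (adjusted p = 0.0709, and 0.025 with the added-array term, with 11 members above 0). The class II genes RT1-Bb at 1.80 (SE 0.126) and RT1-DOb at 0.93 (SE 0.122) were higher, the 2 rises among 34 RT1 genes, a family of near-identical copies whose probes may be shared. The largest other falls were Ly6g6e at -1.77, Ly6g6d at -1.67, Rtn4ip1 at -1.38, the opioid receptor gene Oprk1 at -1.20, Fgd3 at -1.15, Col5a3 at -1.08 and Ly6g6c at -1.08. The largest other rises were the anion exchanger gene Slc26a7 at 2.13 (SE 0.112), the tetraspanin gene Cd9 at 1.63, Arsb at 1.55, the primase subunit gene Prim1 at 1.47, Pter at 1.38, Ccdc107 at 1.37, Cpne7 at 1.37, Rxfp1 at 1.33 and Etfbkmt at 1.25.

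Retinal cell markers differed too. Of 13 bipolar cell genes Car8 was higher at 1.25 (SE 0.137) and Grm6, the glutamate receptor of ON bipolar cells, lower at -0.88 (SE 0.107), while the short-wavelength cone opsin gene Opn1sw was higher at 0.77 (SE 0.11) and the complement gene C1qc, expressed by microglia, higher at 0.67 (SE 0.122). Ribosomal protein (median 0.30, adjusted p = 1.07e-09, adjusted p = 0.582 with an estimated correlation), photoreceptor (0.22, adjusted p = 1.95e-05, adjusted p = 0.582 with an estimated correlation), respiratory chain (0.18, adjusted p = 5.24e-05, adjusted p = 0.879 with an estimated correlation) and antioxidant genes (0.15, adjusted p = 0.00335, adjusted p = 0.582 with an estimated correlation) lay higher in SD by camera. Without F344 room-air pool 2 the adjusted p of both the respiratory chain and the antioxidant list was 0.0515. With the added-array term these medians were 0.23, 0.13, 0.09 and 0.15, SD room-air pool 3 being one of the arrays it covers. The term gave 216 genes. Without F344 room-air pool 2, 19 passed, without F344 room-air pool 1 23, without either SD hyperoxia pool 52, without SD room-air pool 2 48 and without F344 hyperoxia pool 3 121. Tap1 did not pass without either F344 room-air pool (adjusted p = 0.0753 and 0.0562), nor did Arsb, Ccdc107 and Rxfp1. Fgd3 did not pass without F344 room-air pool 1 (0.139) or Ly6g6c without pool 2 (0.22), and Rtn4ip1 passed in 3 of the 10 fits.

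In hyperoxia 68 genes differed, 34 higher and 34 lower in SD (2 SD and 3 F344 pools). Of the genes higher in SD, 28 were also higher in room air, against 0.128 by the product of sizes, and of those lower 16, against 0.0593. Mospd1 at -4.48, Tap2 at -2.45, Ly6g6e at -2.12 and Slc26a7 at 2.22 again led, with RT1-Bb at 1.83, RT1-DOb at 1.25, Rxfp1 at 1.75, Pter at 1.63, Cd9 at 1.45, Prim1 at 1.35, Ccdc107 at 1.32, Tmco3 at 1.27, Arsb at 1.25, Ly6g6d at -1.98, Lix1 at -1.90, Gng11 at -1.35, the alarmin gene Il33 at -1.33 and Fgd3 at -1.30. Grm6 was lower at -1.08 and Car8 and Opn1sw higher at 0.87 and 0.65. Among the 43 hypoxia-inducible factor targets Ankrd37 was lower at -1.30 (SE 0.189, adjusted p = 0.00781) and Pfkfb3 lower at -1.27 (SE 0.241, adjusted p = 0.0442), with 34 members below 0 (median -0.30) and 14 lower adjusted over the list alone (adjusted p = 2.41e-11, adjusted p = 0.569 with an estimated correlation). The list mean was -0.336, and -0.205 without F344 hyperoxia pool 2. In room air that list had a median of 0.10 (adjusted p = 0.0906, and 0.00567 with the added-array term). Ankrd37 did not pass without SD hyperoxia pool 1 (adjusted p = 0.193) or 2 (0.153), nor did Pfkfb3 (0.667 and 0.346), which also did not pass without F344 hyperoxia pool 3 (0.0698), either F344 room-air pool (0.116 each), SD room-air pool 1 (0.0993) or SD room-air pool 2 (0.0964). Arsb did not pass without either SD hyperoxia pool (0.377 and 0.231), F344 hyperoxia pool 1 (0.11) or 2 (0.0789) or either F344 room-air pool (0.0576 each). Ccdc107, Gng11 and Fgd3 did not pass without either SD hyperoxia pool, nor did Prim1 without SD hyperoxia pool 2 (adjusted p = 0.0655). Without SD hyperoxia pool 1 or 2, 21 and 20 genes passed, without F344 hyperoxia pool 2 44, and with the added-array term 126.

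Other lists called between the strains in hyperoxia included respiratory chain genes, which lay lower in SD there (28 of 34 below 0, median -0.15, adjusted p = 0.00335, adjusted p = 0.781 with an estimated correlation) and higher in room air. That call ended without F344 hyperoxia pool 3 (adjusted p = 0.413) or SD hyperoxia pool 2 (0.123). Photoreceptor (median -0.07, adjusted p = 0.64) and ribosomal protein genes (median -0.06, adjusted p = 0.409) were not called in hyperoxia. The interferon and antigen presentation list, with Tap1, Tap2 and Psmb9 its 3 lower members again, was called down (adjusted p = 0.018, adjusted p = 0.569 with an estimated correlation), but not without F344 hyperoxia pool 3 (0.0912) or SD hyperoxia pool 2 (0.0878). Ganglion cell genes lay lower (median -0.09, adjusted p = 0.018, adjusted p = 0.569 with an estimated correlation), a call that ended without F344 hyperoxia pool 2 (0.102) or SD hyperoxia pool 2 (0.0878). Progenitor (median 0.17, adjusted p = 0.018) and cell cycle genes (median 0.12, adjusted p = 0.0181) lay higher (adjusted p = 0.781 each with an estimated correlation). Both calls ended without F344 hyperoxia pool 3 (0.497 and 0.794) or SD hyperoxia pool 2 (0.111 and 0.0878). Cholesterol synthesis genes lay higher (median 0.14, adjusted p = 0.0482, adjusted p = 0.781 with an estimated correlation), but not past the threshold without F344 hyperoxia pool 1 (0.0846), F344 hyperoxia pool 3 (0.274), SD hyperoxia pool 1 (0.081), SD hyperoxia pool 2 (0.123) or SD room-air pool 1 (0.0572). Of these 6 lists, the ganglion cell list was called with the added-array term (adjusted p = 0.00766), while the mean of cell cycle genes turned to -0.008.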

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

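The tests below of single pools, of the arrays numbered 3, of vascular cells, of development, of other tissue, of a batch and of probe mismatches were chosen only after the result was seen; the test of neighbouring genes was not. The rule for the vascular test was also tightened after its value was seen, to ask for the same outcome with and without the added-array term.

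The exposure effect differed between the strains, by camera on the difference of effects, for 7 lists, and none of these calls held with an estimated correlation. The median differences of log2 fold change, SD minus F344, were -0.30 for hypoxia-inducible factor targets, 0.183 for cell cycle genes, -0.283 for photoreceptor genes, -0.108 for antioxidant genes, -0.217 for the unfolded protein list, -0.35 for respiratory chain genes and -0.358 for ribosomal protein genes. The cell cycle difference turned to -0.06 on the scale of the list mean with the added-array term.

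The larger fall of hypoxia-inducible factor targets in SD was weighed first. Over all pools the difference of list means was -0.434 (SE 0.186), and fry gave a directional p of 0.0715. Camera with an estimated correlation gave an adjusted p of 0.476, and no single gene passed. Variation between pools therefore stays open as an explanation. The difference of effects is the gap between strains in hyperoxia less that in room air. The list mean, SD minus F344, was -0.336 in hyperoxia and 0.098 in room air. In room air camera did not call the list (adjusted p = 0.0906), but did with the added-array term (0.00567). Without F344 hyperoxia pool 2 the difference of list means was -0.302 (SE 0.087), and with the added-array term it was -0.536 (SE 0.192). Both lay below 0 by more than 2 SE, so its direction did not rest on that pool, or on the added arrays, alone. That pool was picked because its values stood high on this list. Leaving it out lowers the SE for that reason, so the smaller SE is no added support. A greater loss of vascular cells in SD stays open: endothelial and pericyte genes together differed by 0.019 (SE 0.089) with the term, and the hypoxia list differed from them by -0.555 (SE 0.229) with the term but by -0.344 (SE 0.271) without it. A strain difference in the response to oxygen, which the design names, stays open as a hypothesis, and so does the phase of the oxygen cycle at collection, which the labels used here do not give.

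The 2 arrays numbered 3 stood apart in the same way, their deviations from the group means correlating at 0.643. Dilution of the retina by RNA of other eye tissue would lower neuronal genes along with the cell cycle genes (-0.375). The 71 photoreceptor, ganglion and amacrine genes had a median of 0.125 (SE 0.053), with list medians of 0.15, 0.05 and 0.125. This argues against dilution alone as the cause of the cell cycle fall, within the limit of 2 arrays. Each SE in this paragraph is over genes, which are not independent replicates. Some RNA of other tissue stays open for the higher fibroblast (0.35), surface epithelium (0.15), lens (0.125) and endothelial (0.175) medians: the 50 fibroblast, surface epithelium and lens genes had a median of 0.35 (SE 0.108) in SD room-air pool 3 and of 0 (SE 0.056) in F344 hyperoxia pool 3, against the other arrays of their groups. Retinas further along in development and a batch of preparation or hybridisation cannot be told apart: no batch is recorded in the sources used here, and the 6 of 6 placements of cell cycle and progenitor lists below, and photoreceptor lists above, the other arrays of their groups are what prompted the idea of development and do not test it.

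Strain differences in room air lay close together mainly in the histocompatibility region. Of 79 genes, 11 had another called gene among the 5 nearest measured genes on either side, against a median of 4 and a highest of 14 in 1000 random draws, of which 95% gave at most 8. This is consistent with inherited segments, and rested on the histocompatibility region (Tap1, Tap2, Psmb9, RT1-Bb, RT1-DOb, Ly6g6c, Ly6g6d, Ly6g6e and Msh5): without the RT1, Tap, Psmb and Ly6g genes 2 of 71 had such a neighbour. Probe mismatches at strain variants cannot be told apart from expression without probe sequences and strain genomes; 44 genes differed the same way in room air and hyperoxia, which either would give.

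For the average effect of exposure, 100 relabelings of the pools within strains were counted, the real one included. Only 1, the real one, gave as many as 9 genes, and the highest other gave 1. This argues against chance assignment of pools for this count, but does not exclude it. As the real one is among the 100, the share cannot fall below 1 of 100. The real count also depended on single pools. It was 1 without SD room-air pool 2, 20 without F344 hyperoxia pool 2 and 30 with the added-array term.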

How the results depend on the processing

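The added-array term in list tests, the correlation and single genes, and every fit with that term but without F344 hyperoxia pool 2, were chosen only after the result was seen. The cause of each move below was not tested, including where fewer arrays or fewer genes entered. Repeated quantile normalization kept all counts within 1.5 times, as did median centring and trend and robust eBayes; the difference of effects had 0 genes under each alternative run for that count, which leaves out the fit with only the groups compared and the mean of a gene's probe sets. In the order SD, F344, average, room air and hyperoxia, the counts (7, 1, 9, 79 and 68) became 17, 2, 30, 216 and 126 with the added-array term, 19, 2, 25, 159 and 157 with array weights, and 1, 0, 2, 91 and 56 without the arrays numbered 3. With the replicate number as a block they became 14, 2, 26, 172 and 110. The numbers were not found to pair pools: among the first 8 arrays, deviations of equal number correlated between -0.0529 and 0.149, while the 2 arrays numbered 3 correlated at 0.643. With only the groups compared, SD gave 0, F344 0, room air 10 and hyperoxia 12. The brighter probe sets gave 0 in F344 and 43 in hyperoxia, and 1 probe set per gene 16 for the average. A threshold of 0.1 gave 16 for the average, 151 in room air and 104 in hyperoxia. Without F344 hyperoxia pool 2 and with the term, the first 3 counts were 13, 0 and 24.

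With each array left out in turn the counts ranged from 1 to 9 in SD, 0 to 1 in F344, 1 to 20 for the average, 19 to 121 in room air and 20 to 81 in hyperoxia. A lone pool left in a group was assumed to vary like the other groups. The correlation of effects ranged from -0.332 to 0.0435; it was 0.0237 without the arrays numbered 3, -0.0554 without SD room-air pool 3 and -0.00951 with the term.

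Of 186 list tests 58 were called, 41 down and 17 up. With an estimated correlation 0 were, with fry 0 by the directional and 14 by the mixed p. List means turned direction as follows. Cell cycle went to -0.018 in SD without the arrays numbered 3, and to 0.066 in F344 and -0.008 in hyperoxia with the block or the term. For the difference it went to -0.06 with these or without the arrays numbered 3. Without F344 hyperoxia pool 2 and with the term it went to -0.042 for the difference. In that fit the mean in hyperoxia, 0.007, kept its sign, and only the direction by camera turned. Progenitor genes went to -0.166 for the difference with the block, the term or without the arrays numbered 3. Fibroblast genes went to 0.078 in SD and -0.117 in room air without those arrays. For lens genes in F344 only the direction by camera turned, without pool 2 and with the term, where the mean change was -0.432. Their mean lay lower in F344 hyperoxia before as well (5.229 against 5.254 in room air). With single arrays left out, cell cycle in SD ranged from -0.018 to 0.21, and fibroblast genes from -0.322 to 0.078 in SD, -0.151 to 0.049 on average and -0.117 to 0.283 in room air, the turned end of each lying without SD room-air pool 3. Signal over background was not analysed here, so what dim probe sets limit is not known.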

Other observations

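The comparisons of F344 hyperoxia pool 2 and of SD room-air pool 3 with other pools were chosen only after the result was seen, as were the list tests with the added-array term, while the other tests of the lists were not.

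Signalling and metabolic groups outside the hypoxia response moved by small amounts in SD. Of 16 cholesterol synthesis genes 14 lay above 0 (median 0.16, adjusted p = 0.00689, adjusted p = 0.383 with an estimated correlation), led by Lss at 0.35 (SE 0.218) and Cyp51 at 0.28 (SE 0.135), with 0 passing. Without SD room-air pool 3 this call ended, as did that of the next list (adjusted p = 0.179 each). The calls of cholesterol (0.077), immediate early (0.0682) and microglia genes (0.117) in SD also ended with the added-array term, and cholesterol genes were called in F344 (0.00463). Of 24 immediate early genes 19 lay below 0 (median -0.13, adjusted p = 0.00242, adjusted p = 0.375 with an estimated correlation), among them Dusp6, a phosphatase induced by growth factor signalling, at -0.43 (SE 0.147) and Atf3 at -0.37 (SE 0.103). The clock repressor gene Bhlhe40 stood at -0.70 (SE 0.16) in SD and at 0.28 in F344, in a circadian list with a median of -0.07 in SD (adjusted p = 0.0402, adjusted p = 0.387 with an estimated correlation). Ganglion cell genes had a median of -0.03 and a mean of -0.117 (adjusted p = 0.0136, adjusted p = 0.314 with an estimated correlation), with Sncg at -0.58 (SE 0.173) and the neurofilament gene Nefm at -0.52 (SE 0.259). Microglia genes (median -0.07, adjusted p = 0.0272, adjusted p = 0.375 with an estimated correlation) held Fcer1g at -0.62 (SE 0.268) and C1qc at -0.47 (SE 0.122). Without SD hyperoxia pool 2 the circadian, ganglion cell and microglia calls ended (adjusted p = 0.0708, 0.0624 and 0.214), and they also ended without SD room-air pool 2 for circadian and ganglion cell genes (0.277 and 0.129), without SD hyperoxia pool 1 for circadian genes (0.0837) and without SD room-air pool 3 for microglia genes (0.282). Mt1, a metallothionein of the antioxidant list, stood at -0.83 (SE 0.188) in a list not called in SD (median -0.05, adjusted p = 0.141).

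Groups that camera did not call in SD or in F344 without the added-array term included amacrine and horizontal (medians -0.06 and 0.05), bipolar (0.05 and 0.03), progenitor (0.02 and 0.10) and pigment epithelium genes (0.04 and -0.03), in the last of which Tyr, the pigment enzyme tyrosinase, stood at 1.10 (SE 0.411) and Tyrp1 at 0.82 (SE 0.287) in F344. The same held for erythroid (-0.05 and -0.01), skeletal muscle (-0.03 and -0.02), p53 (0.06 and 0.04), interferon (-0.07 and -0.07), inflammatory cytokine (-0.05 and -0.02) and RT1 genes (-0.02 and -0.08). With the term, pigment epithelium genes were called up in SD (adjusted p = 0.00603), progenitor genes up in F344 (0.0241) and RT1 genes, a family of near-identical copies, down in F344 (0.0212). The pigment epithelium mean was 6.106 in SD hyperoxia pool 1 and 5.9 in pool 2, against 5.789, 5.894 and 6.1 in SD room-air pools 1, 2 and 3. Called in SD and not in F344, with the difference of effects not called, were astrocyte (-0.12 and 0.08), lens (-0.18 and -0.02), surface epithelium (-0.07 and 0) and fibroblast genes (-0.22 and -0.03). Their adjusted p in SD lay between 0.0136 and 0.0428, and between 0.375 and 0.524 with an estimated correlation. Means had the other sign from the medians in F344 for fibroblast (0.019), inflammatory cytokine (0.01) and pigment epithelium genes (0.122), and camera the other sign for lens genes. Without SD hyperoxia pool 2 or SD room-air pool 3 all 4 calls ended (adjusted p from 0.0624 to 0.807), as did that of astrocyte genes without SD room-air pool 2 (0.156). All 4 also ended with the added-array term (astrocyte 0.104, lens 0.077, surface epithelium 0.194 and fibroblast 0.377), and fibroblast genes were called down in F344 instead (0.00639). That call rests on the term, which assumes an equal shift in both arrays numbered 3. Against the other arrays of their groups, fibroblast genes had a median of 0.8 in SD room-air pool 3 and 0.025 in F344 hyperoxia pool 3. Fibroblast means were 5.428, 5.506 and 5.517 in F344 hyperoxia, against 5.456 and 5.472 in F344 room air. SD room-air pool 3 held the highest lens (5.807) and fibroblast (6.083) means of all 10 arrays, and without that pool the fibroblast mean change in SD was 0.078.

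F344 hyperoxia pool 2 differed from pools 1 and 3 for some genes only. The labels used here do not say in which phase of the oxygen cycle the rats of any pool were collected. For Igfbp2 it stood at 7.4, near pools 1 and 3 (7.1 and 7.5) and below room air (8.2 and 8.2), and for Adra1b at 5.5, against 5.5 and 5.7 in the other pools and 6.5 and 6.7 in room air. All 7 genes that fell in SD were below the F344 room-air mean in it (median -0.40). For Hk2 it stood at 8.2 against 7.1 and 6.7 in the other pools, for Pfkfb3 at 9 against 7.9 and 8.2, and for Egln3 at 7.2 against 6 and 6.5. Of the 43 hypoxia-inducible factor targets, 26 were above the room-air mean in it. Its lens mean (5.6) was the highest of the F344 pools.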
